A study of Saccharomyces cerevisiae and Homo sapiens with 25 samples.

How the data were processed

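The measurements are DMS-seq libraries of human K562 cells and primary fibroblasts, treated in vivo, in vitro after refolding, or after denaturation. Per the labels, total RNA was fragmented and ligated to a linker, the prematurely stopped reverse transcription products were selected by size, and the products were circularised and amplified by PCR. The deposited files give counts, that is the raw number of reads at each position of each RefSeq transcript, with positions from 0 and without positions that had no read, and the authors applied no scaling to them. The submitters' processing notes name the build hg19. The aligner and the treatment of reads that match several transcripts are not given in the sources used here. The base that a position marks (the stop or the modified base) is likewise not given, so no base identity is attached to a position. The 18 yeast samples of the series were not analysed here.

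Samples were grouped by cell type and condition from their labels. The labels do not say whether the 2 K562 in vivo libraries came from separate cultures, and they differ in DMS volume. The in vitro and denatured conditions have 1 library per cell type.

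Windows of 50 positions that do not overlap were laid along every transcript. A window was kept when each library compared had a mean of at least 15 counts per position. Since the Gini index rises when depth falls, each window was thinned at random (fixed seed) to the lowest total of the libraries compared. The Gini index was computed over all positions of the window, and Pearson r with the denatured library over the same positions. A window counted as structured with a Gini index more than 0.14 above the denatured library and r under 0.55, with 0.2 and 0.45 as stricter limits. Intervals of shares are exact Clopper-Pearson 95% intervals, and intervals of medians are 95% order-statistic intervals over windows. Reads from PCR without molecular identifiers are not independent molecules, so these intervals and the floor of 3 counts cover counting error only.

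The choices of metric, limits, filters, tests, alternatives and the rule for named transcripts were fixed before the data were examined. That plan called for windows of adenine and cytosine positions, which needs transcript sequences; as none were at hand, all positions were used, as the plan allowed. It called for 1 transcript per gene, which needs gene names; every listed transcript was used instead, so isoforms of a gene count separately, and 0 kept windows of any library were identical to another. Untranslated and coding regions were replaced by the first 200, last 200 and remaining positions of mRNAs. The 19 lists of gene symbols and cell type markers written in advance could not be matched to transcript IDs, so none was tested, and RNA classes were taken from the ID prefix. By the rule for named transcripts, those of the Gini fit have an adjusted p under 0.05 and the same sign in both cell types, those of the count fit have the largest log2 fold changes past 0.05, and windows are ranked by the smaller of both cell types' differences; windows lower in vitro were added after seeing the data. Of the items each rule gives, at most 2 each way are printed.

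Transcript means of the Gini index were fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3), with condition and cell type as terms, for transcripts with at least 2 windows in all 7 libraries thinned to the lowest of the 7. This leaves 3 residual degrees of freedom. eBayes estimated the same variance for all transcripts, so all share 1 standard error. Its prior degrees of freedom were infinite, so the p-values use degrees of freedom pooled over all transcripts rather than 3. An interaction of condition and cell type was fitted in addition, with 1 residual degree of freedom. Noncoding RNAs were tested as a class with camera, with a preset correlation of 0.01 and with an estimated one. In each cell type they were also compared with 10000 random lists matched on the total count per transcript. These lists were not matched on length or on counts per position. Counts per transcript were fitted with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F-test), with cell type and condition as terms, and again with DESeq2 1.42.0. P-values were adjusted by Benjamini-Hochberg. The windows were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

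Further settings were added after seeing the data. The dispersion index of each library, the sum of squared counts over the sum of counts, estimates PCR copies. It was taken over positions with reads in transcripts with reads at no more than 2% of their positions, without the highest 0.1% of counts. It was 6.38, 5.96, 2.17 and 4.14 in the K562 in vivo (300 and 400 µl), in vitro and denatured libraries, and 5.03, 3.62 and 1.89 in the fibroblast in vivo, in vitro and denatured libraries. Windows were also thinned to equal counts after division by this index (equal effective counts). Positions above 0.7 times the mean of the 101 positions around them in the denatured library of the other cell type were taken as responsive; where both cell types are fitted together, both denatured libraries were used. Windows then ran over 50 responsive positions. Transcripts of the other cell type were those with at least 50 CPM (counts scaled to a common library total) there and under 0.15% of that level in 1 library of the tested cell type.

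The code was tested on simulated data. With equal rates and a 4-fold difference in depth, the median Gini difference was 0.000121 with thinning and -0.0067 without it. With 5 PCR copies in one library and 2 in the other, thinning of reads left a false difference of -0.0136, which was -1.04e-05 after thinning to equal effective counts. In that last setting a true difference of 0.0484 was measured as 0.0433. The simulation was given the true copies, so the estimate of copies by the dispersion index was not tested. limma recovered 20 of 50 transcripts with a shift of 0.02 and 50 of 50 with 0.04, with 1 false call. The simulated noise was independent, with the same SD for all transcripts and no shift common to a whole library. That false call therefore does not measure the error rate in the real libraries. edgeR recovered 40 of 100 transcripts changed 2-fold and 89 of 100 changed 4-fold, with 3 false calls, and DESeq2 recovered 49 and 87, with 26 false calls.

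Alternatives covered the thinning, the minimum count, the window width, the highest positions, the limits, the minimum of windows, the eBayes trend, subtraction of the denatured library, each library left out, and for counts the tool, the size factors, the filter and the covariate. Transcripts linked to the sex chromosomes were left out of the listed counts by a list of transcript IDs, which was written from general knowledge and may be incomplete.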

Results

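DMS-seq was used to probe RNA structure in human cells. Dimethyl sulfate (DMS) methylates adenines and cytosines that are not paired, reverse transcriptase stops at the methylated base, and the number of stops at each transcript position reports how open that base was. The labels list 25 samples, of which 18 are yeast samples that were not used here. The other 7 samples are human, with 4 libraries from K562, an erythromyeloblastoid leukaemia cell line, and 3 from primary fibroblasts. K562 had 2 libraries of cells treated in vivo, with 300 and 400 µl of DMS in 15 ml of culture, and 1 library each of RNA treated in vitro after refolding and of denatured RNA. Fibroblasts had 1 library for each of these 3 conditions, so no replicates within a condition.

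The K562 in vivo libraries held 272961199 counts (300 µl) and 118260770 counts (400 µl). The K562 in vitro library held 129567204 counts and the K562 denatured library 316247747. The fibroblast libraries held 82464281 counts in vivo, 149546182 in vitro and 88595960 after denaturation. In the K562 denatured library positions with 2 counts were 2.02 times as frequent as positions with 1 count, against 0.501 to 0.898 times in the other libraries. The reason is not known, and this library is the reference for the structured windows of K562. Counts fell on 24094 RefSeq transcripts, of which 18528 were mRNAs and 3884 noncoding RNAs by their ID prefix. The files do not pair the transcript IDs with gene names, so transcripts are named by ID, and few are listed.

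With all positions, refolded and denatured RNA gave like position profiles in both cell types. Over 3850 windows of 50 positions with enough counts in all 7 libraries, the median Pearson r between the position profiles of the K562 and fibroblast in vitro libraries was 0.964 (quartiles 0.942 to 0.978). The median r between the 2 denatured libraries was 0.956. The fibroblast in vivo library had a median r of 0.933 with the K562 in vivo library at 300 µl and 0.919 with that at 400 µl. At equal effective counts the in vitro pair stayed highest at 0.930. The denatured pair (0.904) then lay below the in vivo ones (0.909 and 0.906). The K562 in vivo libraries had medians of 0.916 and 0.918 with K562 in vitro RNA, and at responsive positions with equal reads (positions with signal above 0.7 times the local mean in denatured RNA) they were closer to it (0.765 and 0.757) than to the fibroblast in vivo library (0.715 and 0.665). At responsive positions with equal effective counts the library at 400 µl stayed closer to K562 in vitro RNA (0.668 against 0.627). The library at 300 µl was about as close to both (0.628 against 0.622). In that setting the in vitro pair had a median r of 0.740 and the denatured pair 0.508, below the in vivo pairs. Over all positions at equal effective counts both K562 in vivo libraries were closer to the fibroblast in vivo library (0.909 and 0.906) than to K562 in vitro RNA (0.877 and 0.890). Within a cell type the profiles of refolded and denatured RNA were less alike, with a median r of 0.835 in K562 and 0.825 in fibroblasts. These correlations are across positions of single windows, and positions are not independent replicates.

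In K562 cells the comparison asked whether RNA had less structure in cells than after refolding in vitro. The Gini index measures how unevenly the counts of a window are spread over its positions, and pairing of part of the bases raises it. Over 13576 windows of 1370 transcripts the median Gini index was 0.623 in denatured RNA, 0.659 and 0.662 in the in vivo libraries at 300 and 400 µl, and 0.672 in vitro. The median difference in vitro minus in vivo was 0.0151 for the library at 300 µl and 0.0121 for that at 400 µl, with a mean of 0.0136 ± 0.0021 (SD, n = 2). Both differences use the same in vitro library. This SD therefore holds the spread of the in vivo libraries, which differ in dose, and none of the in vitro condition. The index was higher in vitro in 68.4% and 64.4% of the windows. With a minimum of 5 counts per position the difference was 0.00983 at 300 µl but -0.000471 at 400 µl, where 49.5% of windows were higher in vitro. The in vitro profiles also differed more from the denatured ones, with a median r of 0.834 against 0.892 and 0.874 in vivo.

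Structured windows, defined by a Gini index more than 0.14 above the denatured library and an r with it under 0.55, were rare in K562. They numbered 28 of 13576 in vitro (0.206%, exact Clopper-Pearson 95% interval 0.137 to 0.298%). In vivo they numbered 12 at 300 µl (0.0884%, 0.0457 to 0.154%) and 9 at 400 µl (0.0663%, 0.0303 to 0.126%). The share in vitro minus the mean in vivo was 0.129 percentage points. With the stricter limits of 0.2 and 0.45 the difference was 0.

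Fibroblasts gave the same direction with a smaller size. Over 12400 windows of 676 transcripts the median Gini index was 0.616 in denatured RNA, 0.642 in vivo and 0.646 in vitro. The median difference in vitro minus in vivo was 0.00546 (95% interval of the median 0.00468 to 0.00631), and 55.8% of windows were higher in vitro. The median r with denatured RNA was 0.823 in vitro and 0.880 in vivo. Structured windows numbered 11 in vitro (0.0887%, exact interval 0.0443 to 0.159%) and 4 in vivo (0.0323%, 0.00879 to 0.0826%), intervals that overlap. The fibroblast difference changed sign to -0.00906 with a minimum of 5 counts per position and to -0.00182 without the 2 highest positions of each window.

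Reactive positions alone gave a wider separation of in vitro from in vivo libraries, in a comparison chosen after seeing the data. DMS acts on adenine and cytosine, and no transcript sequence was at hand to pick them. Positions above 0.7 times the local mean in the denatured library of the other cell type were used in their place (38.2% of positions for K562 and 38.5% for fibroblasts), and the libraries were thinned to equal counts after division by a dispersion index that estimates PCR copies. In K562 the median Gini index over 6344 windows was then 0.353 in denatured RNA, 0.401 and 0.387 in vivo at 300 and 400 µl, and 0.473 in vitro. In fibroblasts it was 0.356, 0.402 and 0.457 over 7639 windows. Structured windows made up 18.1% in vitro against 2.59% and 1.94% in vivo in K562, and 16.4% against 2.20% in fibroblasts. Positions were kept for their signal in denatured RNA, which evens out profiles that resemble the denatured one, the in vivo profiles more than the in vitro ones, so part of the wider gap can follow from the choice of positions.

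**Figure D1:**
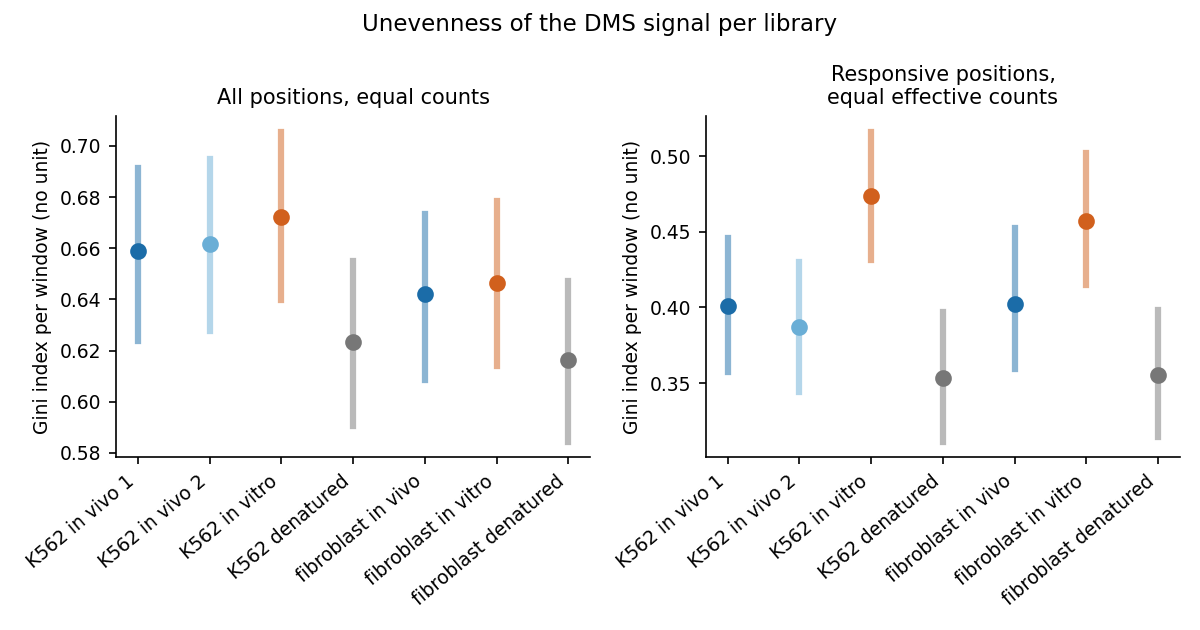
Gini index per window (vertical axis, no unit) in each of the 7 libraries, with all positions on the left and responsive positions at equal effective counts on the right. Points are medians and bars the quartiles over windows. In both panels the in vitro library lies above the in vivo libraries of its cell type (0.672 against 0.659 and 0.662 in K562, and 0.646 against 0.642 in fibroblasts, on the left), and the denatured library lies lowest.

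The DMS dose was compared between the 2 K562 in vivo libraries, the sole pair from a single condition. Over 24039 windows their position profiles had a median r of 0.953. The median Gini index was 0.667 at 300 µl and 0.672 at 400 µl, a median difference of 0.00436 (95% interval 0.00406 to 0.00472). The sign depended on how PCR copies were treated, since the difference was -0.00403 at equal effective counts.

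Transcripts were compared in vitro and in vivo across both cell types with limma, for the 346 transcripts with at least 2 windows in all 7 libraries. The mean Gini index was higher in vitro for 82 transcripts and lower for 7 at an adjusted p of 0.05, and the median difference over all 346 was 0.0122. In 207 transcripts the index was higher in vitro in all 3 comparisons with an in vivo library, and in 22 it was lower in all 3. Both K562 comparisons use the same in vitro library, so the 3 are not independent. NM_014302.3 rose most, by 0.0610 ± 0.00898 (SE; limma adjusted p = 6.43e-09), from 0.637 and 0.625 in vivo to 0.707 in vitro in K562 and from 0.626 to 0.669 in fibroblasts. NM_006713.3 rose by 0.0541 ± 0.00898 (limma adjusted p = 4.13e-07). NM_001190470.1 fell by 0.0520 ± 0.00898 (limma adjusted p = 1.07e-06), from 0.827 and 0.830 to 0.773 in K562 and from 0.769 to 0.724 in fibroblasts. NM_025099.5 fell by 0.0403 ± 0.00898 (limma adjusted p = 0.00021). Each of these 4 transcripts had the same sign in 3 of 3 comparisons, which the rule for naming them largely sets. Their p-values rest on a variance pooled over the 346 transcripts. With 1 in vitro library per cell type, they do not cover a shift of a whole library.

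Against denatured RNA the index was higher in vivo for 260 of the 346 transcripts and higher in vitro for 297, with 1 lower in vitro (limma). At equal effective counts the in vivo count was 118, with 3 lower, and the in vitro count 274, with 1 lower. Without the K562 in vitro library the median difference over the 346 transcripts was 0.0046, with 61.8% of transcripts higher in vitro. Without the fibroblast in vitro library it was 0.02001, with 90.2% higher. Both fits leave 1 in vitro library and have the same degrees of freedom, so these do not account for the gap. With all positions the size of the difference thus depended on which in vitro library was kept. In the fit without the K562 in vitro library NM_014302.3 had a difference of 0.0427 and NM_006713.3 of 0.0451. NM_001190470.1 had -0.0538 and NM_025099.5 had -0.0491. At responsive positions and equal effective counts, an alternative chosen after seeing the data, 699 of 748 transcripts were higher in vitro and 0 lower (0 also at an unadjusted p under 0.05). NM_001190470.1 and NM_025099.5 were not among these 748. Without the K562 in vitro library the median difference over the 748 was 0.0606, against 0.0705 with it.

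Single windows with a higher Gini index in vitro in both cell types were ranked by the smaller of the 2 differences. The window at positions 400 to 449 of NM_001012.1, counted from 0 as in the files, had a difference of 0.157 in K562 and 0.138 in fibroblasts. Its index was 0.661 and 0.655 in vivo and 0.815 in vitro in K562, and 0.623 in vivo and 0.761 in vitro in fibroblasts. The window at positions 1400 to 1449 of NM_170707.3 had differences of 0.142 and 0.134. Windows with the index lower in vitro were named after their values were seen. They lay at positions 1150 to 1199 of NM_213611.2, with -0.105 in K562 and -0.111 in fibroblasts, and at positions 2650 to 2699 of NM_005063.4, with -0.0969 (-0.0543 at equal effective counts) and -0.102. Of 3850 windows 48.2% were higher in vitro in both cell types, against 41.0% if the cell types were independent, and 19.3% were lower in both. Across these windows the differences in the 2 cell types correlated with a Pearson r of 0.530 and a Spearman rho of 0.498. Windows are not independent replicates.

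Along mRNAs the difference was larger near the start of the transcript than near its end. In K562 the median difference in vitro minus in vivo was 0.0208 (95% interval 0.0190 to 0.0233) in the first 200 positions, 0.0141 (0.0134 to 0.0149) between the ends and 0.00993 (0.00806 to 0.0117) in the last 200 positions. In fibroblasts it was 0.00828 (0.00509 to 0.0115), 0.00570 (0.00488 to 0.00662) and 0.000641 (-0.00252 to 0.00368). At equal effective counts the fibroblast values were 0.0190, 0.0177 and 0.00953. Without the 2 highest positions they were 0.00298, -0.00152 and -0.00826, so the order of the regions stayed but the sign did not. The ends stand in for untranslated regions, whose bounds are not in the files.

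Noncoding RNAs differed from mRNAs in K562. Over 68 noncoding transcripts the median of the difference in vitro minus in vivo was -0.0106, against 0.0138 in mRNAs. It lay below all 10000 random lists of transcripts matched on total count. The lists were not matched on length or counts per position, so their percentiles do not separate RNA class from these. Noncoding RNAs under 200 positions had a median of -0.0245, with 30 of 41 below 0. The 27 longer ones had a median of 0.00220, at percentile 0.36 of their random lists, but at percentile 27.9 without the 2 highest positions of each window (0.00263). At equal effective counts the longer ones had a median of 0.0133 and all 68 a median of -0.000855, against 0.0237 in mRNAs. Without the 2 highest positions the median of all 68 was -0.00265, against 0.00412 in mRNAs. Counted by windows, the noncoding median was 0.00207 (95% interval -0.00310 to 0.00587), so the medians over transcripts and over windows differed in sign. In the limma camera test, which held only 6 noncoding transcripts across both cell types, their difference was lower than that of the other transcripts (p = 0.0351 with a preset correlation; p = 0.119 with an estimated correlation; neither an exact test). In fibroblasts 14 noncoding transcripts had a median of -0.00998, at percentile 4.97 of the random lists, and of 0.00901 at equal effective counts (percentile 15.9).

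**Figure D2:**
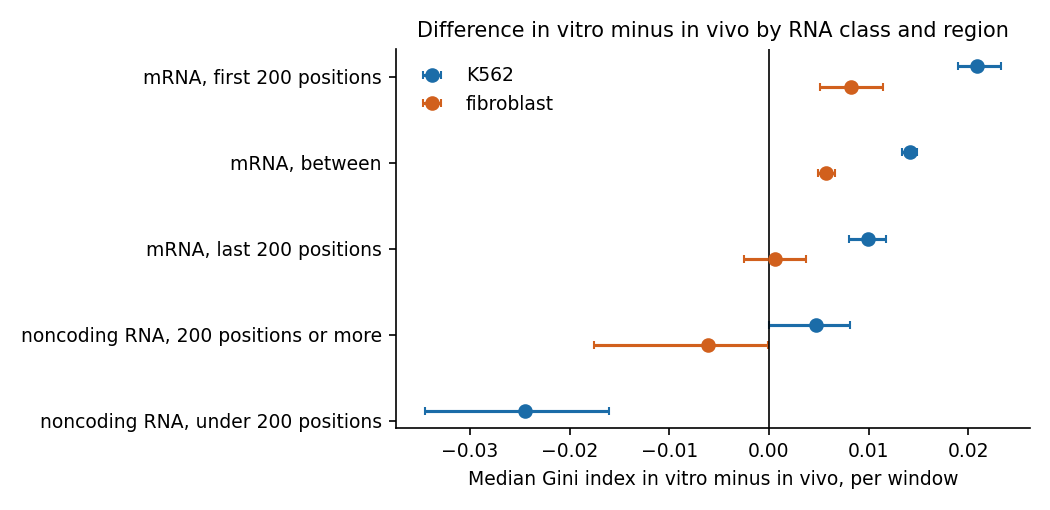
Median Gini index in vitro minus in vivo per window (horizontal axis, no unit) for 3 regions of mRNAs and 2 length classes of noncoding RNA, in K562 and fibroblasts. Bars are 95% intervals of the median over windows, and the fibroblast class with under 20 windows is not drawn. In mRNAs the K562 medians fall from 0.0208 in the first 200 positions to 0.00993 in the last 200, and short noncoding RNAs lie below 0.

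The summed counts per transcript were compared between K562 and fibroblasts as a description of the RNAs behind the structure values. A count of stops follows the abundance of a transcript and its reactivity together. Of 18500 transcripts tested with edgeR, with condition as a covariate, 6787 were higher and 6514 lower in K562 at an adjusted p of 0.05. NM_016204.1 had 1450 counts over the K562 libraries (1.70 ± 0.630 CPM, that is counts scaled to a common library total, SD, n = 4) and 0 in fibroblasts, which makes it at least 185-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.000506). NM_139317.1 was at least 131-fold higher (edgeR adjusted p = 0.00206). NM_006896.3 had 517 counts in fibroblasts (1.67 ± 0.279 CPM, SD, n = 3) and 0 in K562, at least 449.9-fold lower (edgeR adjusted p = 0.00154). NM_002422.3 had a log2 fold change of -10.87 ± 1.10 (SE; edgeR adjusted p = 0.000322), with 1.33 ± 1.30 CPM in K562 and 646 ± 32.7 in fibroblasts. The fold change was -12.21 without the fibroblast in vivo library, -9.71 without the K562 denatured library, -9.72 without the fibroblast denatured library and -9.40 without the covariate, so its size depended on the fit, and the summed counts of both groups gave a 554-fold lower level. Its K562 counts stand beside those of other fibroblast transcripts, which had a median of 0.360% and 0.499% of their fibroblast level in the K562 in vivo libraries. Each of these 4 transcripts had its direction in 4 of 4 K562 libraries against the fibroblast mean, which their choice by the largest fold changes largely sets.

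Noncoding RNAs and predicted RNAs carried more counts in K562. Of 2252 noncoding RNAs tested, 987 were higher and 380 lower in K562 (edgeR), with a median log2 fold change of 1.10. Of 15389 mRNAs, 5454 were higher and 5982 lower, with a median of 0.01. Predicted RNAs shifted like the noncoding ones, with medians of 1.15 (ID prefix XM, 212 tested) and 0.994 (XR, 647 tested). The shift was thus not particular to noncoding RNAs. The camera test placed noncoding RNAs above the rest (p = 2.36e-05 with a preset correlation), which was lost with an estimated correlation (p = 0.244).

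Low counts of the other cell type's transcripts were present in the in vivo libraries and in fibroblast denatured RNA. The 284 transcripts high in fibroblasts and lowest in K562 denatured RNA stood at a median of 0.360% of their fibroblast level in the K562 in vivo library at 300 µl (quartiles 0.316 to 0.414%) and at 0.499% in that at 400 µl. Their median was 0.101% in the K562 in vitro library. In the fibroblast libraries 61 transcripts high in K562 and lowest in fibroblast in vitro RNA stood at 2.47% of their K562 level in vivo (quartiles 2.21 to 2.69%), 0.943% in denatured RNA and 0.0908% in vitro. The denatured K562 and in vitro fibroblast values are low because the lists were chosen on them.

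**Figure D3:**
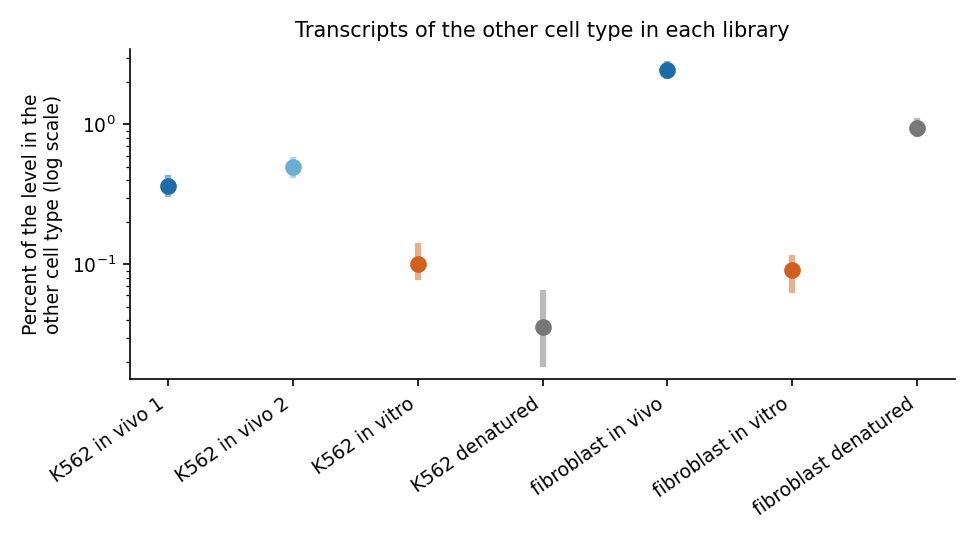
Level of the other cell type's transcripts in each library, as a percent of their mean level in the cell type they come from (vertical axis, log scale). Points are medians and bars quartiles over 284 fibroblast transcripts in the 4 K562 libraries and 61 K562 transcripts in the 3 fibroblast libraries. The fibroblast in vivo library lies highest at 2.47%, and the lists were chosen on the K562 denatured and fibroblast in vitro libraries.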

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

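All tests in this part that weigh an explanation were chosen after the result was seen. The difference in Gini index in vitro minus in vivo was itself called different between K562 and fibroblasts for 9 of 346 transcripts, by the interaction term of the limma fit. It was larger in K562 for all 9, and the medians over the 346 transcripts were 0.0188 in K562 and 0.00630 in fibroblasts. At equal effective counts limma called 0 transcripts, with 30 at an unadjusted p under 0.05, while the median difference between the cell types was 0.00805, with 69.7% of transcripts above 0 (0.0120 and 81.5% with equal reads). At responsive positions it called 33, all larger in K562, and at responsive positions with equal effective counts it called 1 (median 0.0203, 77.9% above 0). The fit has 1 residual degree of freedom, and each cell type has 1 in vitro library.

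The higher Gini index in vitro was weighed against PCR copies and depth, a few strong positions, and RNA being less folded in cells. PCR copies and depth are argued against only as far as the dispersion index measures copies. The difference at equal effective counts was 0.0171 in fibroblasts, the smaller of the 2 values, and larger than with equal reads. Against no thinning, this setting left the fibroblast in vivo median at 0.641 and raised the in vitro median from 0.644 to 0.658. An index too high in vivo would widen the difference in the same way, which was not tested. Strong positions are argued against as the whole cause in K562, where 0.00467 stayed above 0 without the 2 highest positions, but may account for the difference in fibroblasts, where it was -0.00182. Less folding in cells stays open as a hypothesis, as at least 73.4% of windows in each in vivo comparison had a lower r with denatured RNA in vitro, without the 2 highest positions; at responsive positions with equal reads the percent was 49.0 for the K562 library at 400 µl. The in vitro libraries also differ from those of cells in bound proteins and in how DMS was given, which were not tested.

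For the counts of transcripts, 34 of the 35 splits of the 7 libraries into 4 and 3 could be fitted with edgeR, and 1 could not because it coincided with a condition. The real split called 13301 transcripts and the highest other split 0, so 1 of 34 splits gave as many. Every other split put K562 and fibroblast libraries in the same group, so the cell type difference widened the spread within groups. Few calls in those splits can follow from this alone, so the test cannot decide whether chance contributed to the count. Nor does it separate cell type from anything else that differed between the K562 and fibroblast libraries.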

How the results depend on the processing

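Settings with effective counts, responsive positions or the other cell type's denatured library were chosen after seeing the data. No paired analysis was possible because the labels share no more than 1 replicate number between groups. Windows of adenine and cytosine against all bases were not run, for lack of sequences, nor were gene lists, coding regions and untranslated regions. Over all results and settings, 168 values moved by less than their spread, stayed within 1.5 times or kept their side of the threshold, 61 moved, 6 no longer passed and 4 reversed. The fibroblast share of structured windows, whose difference lay within its counting interval, also changed sign in 1 setting and is counted among those that moved. Of the values of named transcripts and windows, 110 kept, 6 moved and 4 no longer passed (each of the 4 transcripts without the K562 in vitro library, with differences of 0.0427, 0.0451, -0.0538 and -0.0491 and an adjusted p of 0.149, in a fit with a prior of 4.14 degrees of freedom). Each count between K562 and fibroblasts kept within 1.5 times under all 11 settings run for it. Where no cause is named below, the cause was not tested.

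The median Gini difference in K562 (0.0136) was 0.0168 with a minimum of 30 counts, 0.00468 with 5 (where the comparison with the library at 400 µl alone was -0.000471), 0.00467 without the 2 highest positions, 0.0232 at equal effective counts, 0.0643 at responsive positions and 0.0783 with both. In fibroblasts (0.00546) it was 0.00344 without thinning, 0.0110 with a minimum of 30, -0.00906 with 5, 0.00326 and 0.00647 with windows of 25 and 100 positions, -0.00182 without the 2 highest positions, 0.0171 at equal effective counts, 0.0292 at responsive positions and 0.0522 with both. The dose difference (0.00436) was 0.00688 without thinning, 0.00243 with a minimum of 30, -0.00403 at equal effective counts, 0.0111 at responsive positions and -0.0110 with both.

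The share of structured windows in K562 (0.129 points) was 0.231 with the other denatured library, 0 with stricter limits, 0.0203 and 0.157 with minimums of 30 and 5, 0.303 and 0.0376 with windows of 25 and 100 positions, 0.0295 without the 2 highest positions, 0.166 at equal effective counts, 10.0 at responsive positions and 15.9 with both. In fibroblasts (0.0565 points) it was 0.127 with the other denatured library, 0.137 and -0.0445 with minimums of 30 and 5, 0.252 and 0 with windows of 25 and 100 positions, 0 with stricter limits, 0.00807 without the 2 highest positions, 0.145 at equal effective counts, 10.7 at responsive positions and 14.2 with both. Its 2 values of 0 and that of 0.00807 moved by less than its counting interval, which does not show a kept direction.

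The 82 transcripts higher in vitro were 50 with a minimum of 30 (151 transcripts tested), 575 at responsive positions and 699 with equal effective counts too. Leaving out 1 library gave 0 to 103, with 33 and 38 without each K562 in vivo library, 54 without the fibroblast in vivo library and 0 without the K562 in vitro library, which leaves 1 in vitro library assumed to vary like the others. Without that library, equal effective counts gave 15, and 504 at responsive positions. The fit without the fibroblast in vitro library also leaves 1 in vitro library, with the same degrees of freedom. There 90.2% of the 346 transcripts were higher in vitro, against 61.8% without the K562 in vitro library. The 7 lower transcripts were 11 with 1 window per transcript, 3 with a minimum of 30, 3 at equal effective counts, 1 at responsive positions and 0 with both. At responsive positions the tested set differed (748 transcripts), and NM_001190470.1 and NM_025099.5 were not in it. The low counts there are thus in part an absence of transcripts. Leaving out 1 library gave 0 to 8, with 3 without the K562 in vivo library at 400 µl, and without the K562 in vitro library 2 at equal effective counts and 2 with responsive positions too. Subtracting the denatured library gives the same fit as leaving a denatured library out, by construction.

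The camera p for noncoding RNAs (0.0351) was 0.119 with an estimated correlation and 0.0714 at equal effective counts. The first minus the last 200 positions of mRNAs differed in K562 by 0.0142 at equal effective counts and 0.0167 at responsive positions too, and in fibroblasts by 0.0160 at responsive positions and 0.0131 with both. Depth limits the structure values to 1370 transcripts in K562 and 676 in fibroblasts.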

Other observations

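All tests in this part were chosen after the result was seen. Longer noncoding RNAs (200 positions or more) were compared with mRNAs at responsive positions and equal effective counts, and the result differed between transcripts and windows. In fibroblasts the median Gini index in vivo minus denatured was 0.0864 over 12 noncoding transcripts against 0.0468 in mRNAs. That value lay at percentile 99.9 of 10000 random lists matched on total count, but not on length or counts per position. Over windows the median was 0.0331 against 0.0481. In K562 it was 0.0639 over 15 transcripts against 0.0385, inside the 95% range of random lists (0.0199 to 0.0665), and 0.0427 against 0.0386 over windows. The median in vitro minus in vivo was 0.0634 against 0.0801 in mRNAs in K562 (percentile 2.05) and 0.0510 against 0.0534 in fibroblasts (percentile 30.8). With all positions and equal reads the K562 value in vivo minus denatured was 0.0342 against 0.0364 (percentile 31.9). The fibroblast value, over 10 transcripts, was 0.0212 against 0.0278 (percentile 32.4). At equal effective counts with all positions it was -0.00658 against 0.0104 (percentile 1.38), so the fibroblast direction depended on the positions used.

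Structured windows in vivo made up 1.23% of 447 noncoding windows in K562 (mean of both in vivo libraries) and 0.0381% of 13119 mRNA windows. In fibroblasts they made up 0% of 74 noncoding windows and 0.0325% of 12324 mRNA windows. In vitro the K562 shares were 0.224% of noncoding and 0.206% of mRNA windows. At responsive positions and equal effective counts the K562 noncoding share (135 windows of 17 transcripts) was 10.4% in vivo and 5.19% in vitro. K562 mRNAs went the other way, with 2.09% and 18.4%. Fibroblast noncoding RNAs (87 windows of 13 transcripts) went the way of mRNAs, with 3.45% in vivo and 14.9% in vitro. The differences between the classes were not tested. Of the 447 noncoding windows in K562, 403 came from 27 transcripts of 200 positions or more, the longest of 13333 positions. A few long transcripts can therefore weigh heavily in these shares, which need not describe noncoding RNAs in general.

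Transcripts high in fibroblasts were present at a low level in the K562 in vivo libraries. Low expression in K562 cells is argued against: in 231 transcripts chosen on the K562 in vitro library, the median ratio of in vivo to denatured level was 11.7 at 300 µl and 17.1 at 400 µl, against 1.03 and 0.919 in 4844 transcripts that K562 cells carry. RNA or library molecules from fibroblasts may account for it, since all 284 transcripts of the list had counts in both libraries at a like percent of their fibroblast level, with an SD of the log2 percent of at most 0.340. No biological explanation was tested beyond low expression, and a step at which such molecules could have entered was not tested. K562 transcripts stood higher in the fibroblast in vivo (2.47%) and denatured (0.943%) libraries. All 61 of that list had counts there, with an SD of the log2 percent of 0.261 and 0.234. Explanations for the fibroblast libraries were not weighed.

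Short noncoding RNAs (under 200 positions) had a lower Gini index in vitro than in vivo in K562, with a median of -0.0245 and 30 of 41 below 0. As far as the dispersion index measures copies, PCR copies and depth are argued against as the cause of the sign by a median of -0.0217 at equal effective counts. The interval of the median over windows, -0.0344 to -0.00867, also lay below 0. The 95% range of random lists was 0.00731 to 0.0287, but these were matched on total count and not on length or counts per position. Strong stops at single positions stay open: without the 2 highest positions the median was -0.00496, below the random lists (-0.00117 to 0.0146), but only 23 of 41 were below 0, and the median over windows was -0.00841 with an interval of -0.0227 to 0.0086 that includes 0. The 4 such transcripts measured in fibroblasts gave 4 windows with a median of -0.0435, from -0.122 to 0.0220. No biological explanation was tested.

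The signal along mRNAs was more alike at a distance of 3 positions than at 2 or 4. In K562 denatured RNA the correlation of log counts at 3 positions exceeded the mean of those at 2 and 4 positions by a median of 0.0344 (95% interval 0.0332 to 0.0359) in 3297 mRNAs at least 600 positions from both ends. In 55 noncoding RNAs the excess was 0.0202 (0.00856 to 0.0281), lower by 0.0142. A candidate explanation is the codon composition of coding sequence, which could not be separated from other features of mRNAs without coding bounds. The excess was 0.0227 in the last 600 positions of mRNAs, near the noncoding value, and in K562 in vitro RNA it was 0.0170 in the inner part of mRNAs, within the noncoding interval of -0.0036 to 0.0312. In fibroblast denatured RNA the excess was 0.0468 in 694 mRNAs and 0.0161 (-0.0234 to 0.0585) in 7 noncoding RNAs.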
